A study of Mus musculus with 10 samples.

How the data were processed

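The data are 10 single-colour (Cy3) Agilent mouse exon arrays of total RNA from the left (contralateral) and right (ipsilateral) brain hemispheres of male Swiss mice of 30 to 35 g, 5 arrays per group. Per the labels' protocols, the middle cerebral artery was occluded by ferric chloride on the dura, mice were perfused with saline 6 hours later, RNA had an integrity number above 9, and 50 ng was labelled by random and T7 priming with spike-in controls. Groups and replicate numbers were taken from the sample titles.

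Per the file headers, each scan was converted to spot intensity by Agilent Feature Extraction 10.7.3.1, with probes annotated on mouse build mm9, whereas the submitters' processing notes name version 9.1. The deposited processed intensity of a spot is background-subtracted and spatially detrended within its array and not normalized between arrays, per the file headers. The deposited table of the whole series holds a value per probe that behaves as log2, per a comparison with the scanner signals (slopes of 0.948 to 1.04 and correlations of 0.997 to 0.999 against the log2 signal); the authors' method of scaling it is not given in the sources used here. Its columns have medians of 12.08 to 12.10, probes were matched by name, and it served as an alternative.

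From the files, control spots (8943 of 411345) and spots marked as outliers were left out, saturated spots (0 to 2 per array) were kept, spots of a probe were averaged, and log2 of the processed intensity minus the array's 75th percentile was taken. Of 235712 probes, 235529 were measured on all arrays and 199147 were kept as well above background on at least 5 of 10. Probes were named through their RefSeq accession, without versions, with a table of assembly GRCm38.p6 used for names alone. It matched 23127 of 23574 mRNA accessions and named 203247 probes (86.2%). The 32465 unnamed probes comprised 9039 with Ensembl, 3847 with RefSeq mRNA and 19579 with other identifiers. A gene's value was the mean of its kept probes, whose directions can differ, and 18874 of 20320 genes with a probe were tested. The median difference of all tested genes was −0.04, and no other scaling moved it by over 0.1 or the share of higher calls by over 10 percentage points. A gene well above background on no array of a group was given as a lower bound, the mean of the bright group against the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own.

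Ipsilateral and contralateral arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package, version 1.17.8, for reading, without a block, and an adjusted p under 0.05 by the Benjamini-Hochberg method. The 37 gene lists, of at least 5 tested genes each, were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry. The lists, the rule for named genes, the alternatives and the design were fixed before the data were examined, except as stated. The rule took, among genes past the threshold whose groups did not overlap, the 12 largest rises and 12 largest falls; up to 3 members of each list past the threshold with the largest change, up to 6 for each of the 3 cell cycle lists; Ccnd1, Cdk1, Ccnb1, Mki67, Pcna, Cdkn1a and Trp53 in any case; and, where no member passed, the one with the smallest p. Of the genes this rule names, 3 are not reported here, though the counts include them.

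Both arrays of a replicate number share a slide, so the slide and the replicate number are the same block. Numbers 1 and 2 were scanned on 1 day and numbers 3, 4 and 5 on another. Deviations from the group means correlated within each number (r across genes 0.529, 0.305, 0.623, 0.292 and 0.599 for numbers 1 to 5), each above the highest value with another number (0.435, 0.139, 0.019, −0.039 and 0.224) and above 0.1, so the numbers were taken to pair the samples. That rests on the data, since the labels state no shared animal, and a slide effect would give it too. The main fit, fixed in advance without a block, still gave the values and their SE, which are those of unpaired groups. With the block 350 further genes passed and 39 no longer did. P-values measure the spread between these samples, part of which may be technical.

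The alternatives were quantile and median scaling, normexp background correction (offset 50), no filter or a filter on all 10 arrays, the median or the brightest probe of a gene, the replicate block, the series table, array weights, a variance trend, each array left out in turn, single probes and a 1.5-fold threshold. The files hold no mean signal, so normexp ran on median signals. Added after seeing the data were the scan day as a block, each scan day alone, numbers 3 and 4 left out, number 5 left out, numbers 1 and 5 left out, and the block with an estimated correlation.

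On simulated data for the comparison of hemispheres (200 of 18874 genes changed), the fit recovered 55.2% of genes changed 1.5-fold, 74.6% at 2-fold and 98.5% at 4-fold, with 7 false among 162 calls. With the block it recovered 31.3%, 65.7% and 97.0%, with 9 false among 141. A list shifted by 0.5 was found and 0 others. Here and in the simulation below, values were drawn independently, with neither correlation between genes or probes nor pairs of arrays. The result therefore says little of real lists, whose estimated correlations reached 0.84. Nor do the recoveries with the block bear on paired arrays. Whether transcript records of a gene differed in their response was tested for 1631 genes with several records, as the mean of a record's probes minus that of the gene's other probes; on simulated data it recovered 97.0% of 200 genes at 2-fold, with 11 false among 205 calls. A pair of other forms were tried on the real data before that one, limma's diffSplice, most of whose calls on simulated data were false, and a test of each probe against the gene's others, which recovered none of the simulated genes, and both were dropped for that reason.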

Results

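Gene expression was measured in the brain hemispheres of male Swiss mice 6 hours after thrombosis of the right middle cerebral artery, induced by laying ferric chloride on the intact dura. Total RNA of the right (ipsilateral, occluded) and left (contralateral) hemispheres was hybridised to 10 single-colour mouse exon arrays, 5 per group. The labels give the tissue as cerebral cortex, whereas the protocol describes whole hemispheres. The submitters state 5 independent experiments, and no label states which mouse each sample came from. Between 82.1% and 88.0% of the spots of an array were well above background, the 75th percentile of its signal lay between 714 and 1152 units, and correlations between arrays over genes ran from 0.963 to 0.991, so no array was a copy of another. The number of arrays limits the precision of the values below. They are log2 differences, ipsilateral minus contralateral, ± SE of the fit without a block, with n = 5 arrays per group. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over 18874 genes, and "rose" and "fell" describe genes past an adjusted p of 0.05, ipsilateral relative to contralateral.

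The comparison asks which genes, and in particular which cell cycle genes, differ between the occluded and the opposite hemisphere at this early time. The occluded side was the right one, where ferric chloride lay on the dura, and the samples hold no sham or untreated group. Side, ferric chloride and occlusion therefore cannot be told apart. Genes that rose in the occluded hemisphere included single inflammatory mediators, heat shock proteins and transcription factors. The largest rise was that of Il6, a proinflammatory cytokine, which was at least 17.5-fold higher in the main processing (4.13 ± 0.21, adjusted p = 1.18e-05). It was not well above background on the 5 contralateral arrays. That bound equals its fold there and does not hold across settings. Il6 differed by 3.18 with no filter and by 2.57 with the series table. Of the chemokines that attract neutrophils and monocytes, Cxcl1 was 7.12-fold higher (2.83 ± 0.18), Ccl7 6.86-fold (2.78 ± 0.20), Ccl2 6.38-fold (2.67 ± 0.18) and Ccl3 6.01-fold (2.59 ± 0.32). The inducible heat shock proteins Hspa1a and Hspa1b were 9.68-fold (3.28 ± 0.40) and 6.85-fold (2.78 ± 0.32) higher. Saa3, an acute phase protein, rose by 3.42 ± 0.23 on the log2 scale, and Ptx3, a pentraxin, was 7.06-fold higher and Hcar2, a receptor for hydroxybutyrate and niacin, 6.58-fold higher. Of the contralateral arrays, 4 of 5 measured Saa3 and Hcar2 above background and 3 of 5 measured Ptx3. The sizes moved with the processing, Il6 from 1.29 with normexp to 5.46 with its brightest probe alone. With normexp Saa3 differed by 1.24, Cxcl1 by 1.29, Ptx3 by 1.23, Ccl7 by 1.22, Hcar2 by 1.04, Ascl2 by 2.43, Ccl2 by 1.99, Ccl3 by 1.98 and Fosb by 1.84, each past the threshold. Of 4 probes of Ccl7 and 3 of Ccl3 the brightest alone differed by 0.05 (adjusted p = 1) and 0.65 (adjusted p = 0.326). With the filter on all 10 arrays Ccl7 differed by 0.05 (adjusted p = 0.977). The transcription factors Ascl2 (11.1-fold, 3.47 ± 0.47) and Fosb (5.81-fold, 2.54 ± 0.31) completed the 12 largest rises; the Fosb value of ipsilateral replicate 5, −1.67, lay below the other 4, which ran from −0.38 to 0.03.

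Falls were smaller. Igbp1b was 3.41-fold lower (−1.77 ± 0.32), with 2 of 5 ipsilateral arrays above background, Omd, a matrix proteoglycan, 2.18-fold lower (−1.13 ± 0.20), Chrna10, a nicotinic acetylcholine receptor subunit, 2.16-fold lower (−1.11 ± 0.16) and Ntf3, a neurotrophin, 2.15-fold lower (−1.11 ± 0.24). Of the genes past the threshold, these 4 alone were lower by at least 2-fold. The next 8 fell between 1.86-fold and 1.98-fold and comprised Tcap, Ankrd34c, the galactosyltransferase gene B3galt2, the neuronal transcription factor Bhlhe22 (−0.93 ± 0.14), Ddit4l, Lrrn3 (−0.91 ± 0.12), the Wnt agonist Rspo3 (−0.90 ± 0.14) and the endothelin Edn3. Contralateral replicate 4 of Ankrd34c, at −2.35, lay above its group's other values, the highest of which was −2.46, and ipsilateral replicate 2 of Ddit4l, at −1.64, lay below its group's others, the lowest of which was −1.36. There were 20 other planned settings without a block, 10 of which leave out an array. Ankrd34c and Ddit4l passed in 20, B3galt2, Bhlhe22, Lrrn3 and Rspo3 in 19, Chrna10 in 18, and Omd and Edn3 in 17. Tcap passed in 12, Ntf3 in 11, and Igbp1b in 15 of the 19 that tested it. Igbp1b differed by −0.56 with normexp (adjusted p = 0.0835) and Omd by −0.51, Chrna10 by −0.20 on its brightest probe (adjusted p = 1) and B3galt2 by −0.45 with no filter (adjusted p = 0.623).

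**Figure D1:**
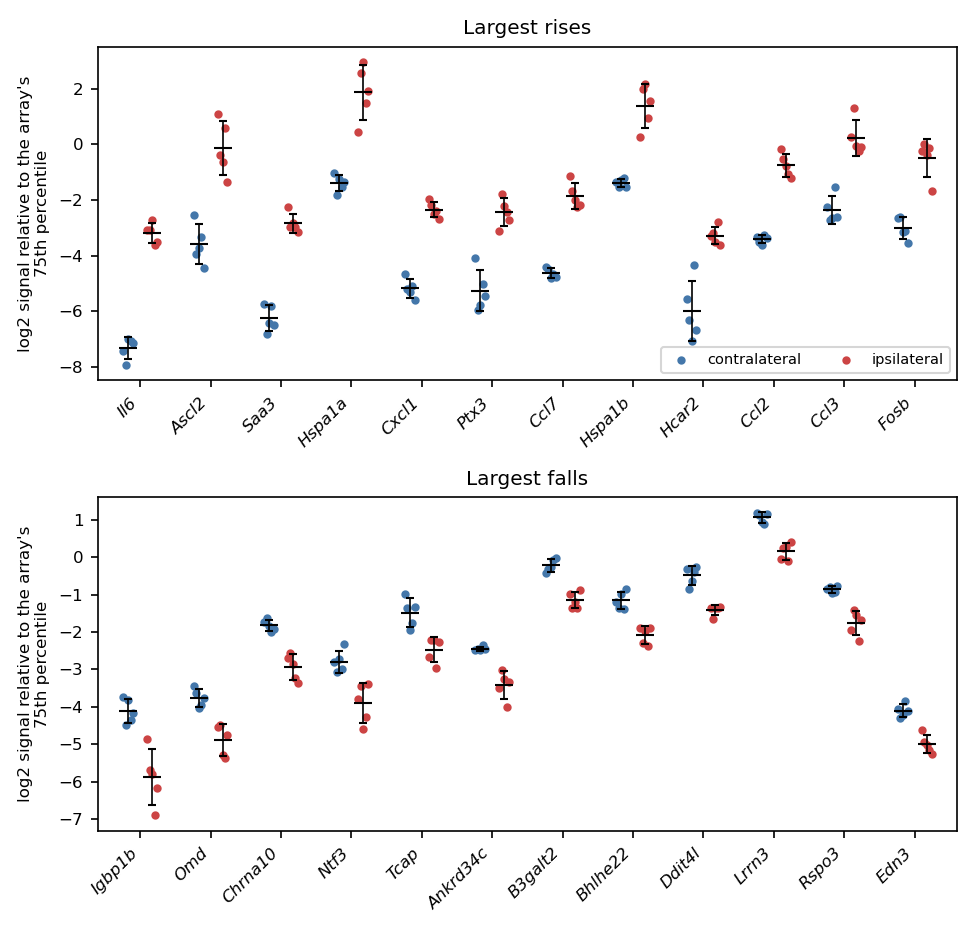
The log2 signal relative to each array's 75th percentile (y axis) for the 12 largest rises (upper panel) and the 12 largest falls (lower panel), with 1 point per array, contralateral in blue and ipsilateral in red, and black bars for the mean ± SD of 5 arrays. The 5 ipsilateral points of each gene lie wholly above or wholly below the 5 contralateral points, as the choice of these genes required.

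In all, 463 of 18874 genes differed at an adjusted p under 0.05, 323 higher and 140 lower, with a median rise of 0.61 and a median fall of −0.46. Of these, 208 changed at least 1.5-fold (174 up, 34 down) and 80 at least 2-fold (76 up, 4 down). The 2 groups of arrays did not overlap in 439 of the 463, and in 5.48% of all tested genes, where chance gives 0.794% for unpaired arrays. The arrays here were taken as paired by number, so that rate is not exact for them. With the replicate number as a block, which here is also the slide, 774 genes differed (526 up, 248 down), and 424 were called in both fits. With the scan day as a block, 445 differed (328 up, 117 down). Within scan day 1 (2 arrays against 2) 10 genes passed and within scan day 2 (3 against 3) 13 did, all of them higher. The count fell by over 1.5 times without contralateral replicate 1 (282), 3 (201), 4 (245) or 5 (208), or without ipsilateral replicate 1 (244), 2 (213) or 4 (211), and the higher and lower counts ranged from 159 to 467 and from 36 to 194 as each array was left out in turn. The lower count alone also moved that far without ipsilateral replicate 3 (92). Without both arrays of numbers 3 and 4, whose ipsilateral samples had low choroid plexus signals, Il6 and Cd14 alone passed. That fit held 3 arrays against 3. In it 1123 genes had an unadjusted p under 0.05 in limma, and 0 of the 463 genes turned direction. Without number 5, which held the array with the highest pituitary signals, 313 genes passed. Number 1 had Gh signals of 4.25 and 1.46. Without numbers 1 and 5 the count was 100, 95 higher and 5 lower. Of 75 named genes past the threshold, 33 stayed past it on the brightest probe of each gene, 54 on the median of its probes and 62 with normexp.

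The study's title names cell cycle genes, and 102 of them, in 3 lists, were tested. Of these, 9 changed, 6 up and 3 down, and 16 passed when adjusted over the lists alone. Among all 18874 genes tested 463 changed, and whether the cell cycle share differs from that was not tested. Of the 6 that rose, 4 were in the list of inhibitors and checkpoint genes. Gadd45b was 4.30-fold higher (2.10 ± 0.39, adjusted p = 0.0207) and Gadd45g 2.47-fold (1.31 ± 0.17, adjusted p = 0.00364), both stress sensors of the growth arrest and DNA damage family. The 2 groups of Gadd45b overlapped, with ipsilateral replicate 5 at 0.31 below contralateral replicate 1 at 0.39. The Gadd45g value of ipsilateral replicate 5, 0.52, lay below its group's other values, which began at 1.26. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was 2.37-fold higher (1.24 ± 0.27, adjusted p = 0.0376), and Btg3, an antiproliferative factor, 1.35-fold (0.44 ± 0.09, adjusted p = 0.0385, 0.0564 with the replicate block). Ccnf, which encodes the ubiquitin ligase subunit cyclin F, was 2.22-fold higher (1.15 ± 0.20, adjusted p = 0.0154) and Kif23, a kinesin of cytokinesis, 1.39-fold (0.48 ± 0.09, adjusted p = 0.0273). Prim1, a DNA primase subunit, was 1.46-fold lower (−0.54 ± 0.08, adjusted p = 0.0077) and Cenpe, a kinetochore kinesin, 1.26-fold lower (−0.33 ± 0.07, adjusted p = 0.0407, 0.0646 with the block). In the 20 settings Gadd45g passed in 20, Ccnf in 19, Prim1 in 18, Gadd45b in 15, Cdkn1a in 11, Btg3 in 9, Kif23 in 8 and Cenpe in 3. With normexp the adjusted p of Kif23 was 0.569 and that of Cenpe 0.367.

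Of the cell cycle genes named in advance, 6 did not pass the test. Mki67 differed by 0.04 ± 0.08, Pcna by −0.02 ± 0.12, Cdk1 by −0.11 ± 0.14 and Ccnb1 by −0.13 ± 0.11, and the tumour suppressor Trp53 by 0.05 ± 0.18; the signs of Mki67, Pcna and Cdk1 turned with the processing, and those of Pcna and Trp53 with the array left out. Ccnd1, cyclin D1, was 1.28-fold higher (0.36 ± 0.10, adjusted p = 0.084) and passed with the block (adjusted p = 0.0491). Of the 34 drivers of the G1 and S phases, 0 rose and 2 fell (5 past when adjusted over the list alone), and with the block 3 rose and 2 fell, the 3 being Ccnd1, Cdk6 and Cdt1. Of the 35 genes of the G2 and M phases, 2 rose and 1 fell (4 over the list alone), and with the block 3 rose and 0 fell, Cenpa being the third. Neither list shifted as a set (camera adjusted p = 0.822 and 0.792), except that the second passed on the brightest probes (0.0264). Of the 33 inhibitors and checkpoint genes 4 rose and 0 fell (10 over the list alone), and the list shifted up (adjusted p = 0.00931, 0.198 with an estimated correlation). Its mean was 0.16 and its median −0.00, with 16 members positive and 17 negative. Its adjusted p was 0.0514 without contralateral replicate 4, 0.0806 without numbers 3 and 4, 0.177 within scan day 1 and 0.00331 within scan day 2. With the replicate block 11 cell cycle genes changed, 9 up and 2 down. The count of 9 was 4 without contralateral replicate 3, 4 or 5 or without ipsilateral replicate 1 or 3, 3 without ipsilateral replicate 2 and 2 without ipsilateral replicate 4.

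**Figure D2:**
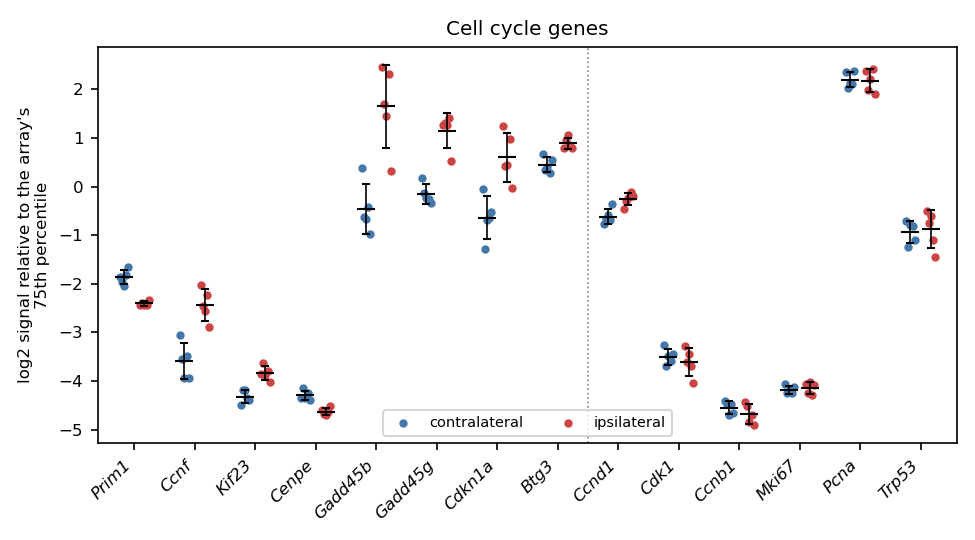
The log2 signal relative to each array's 75th percentile (y axis) for 8 of the 9 cell cycle genes that changed (left of the dotted line) and for 6 that were named in advance and did not pass, with 1 point per array, contralateral in blue and ipsilateral in red, and black bars for the mean ± SD of 5 arrays. The ipsilateral Gadd45b mean of 1.65 stands above the contralateral mean of −0.46, though its 2 groups overlap. The 2 groups of Mki67 lie on each other at −4.14 and −4.18.

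Over the 37 gene lists fixed before the data were examined, 19 shifted as a set at a preset correlation of 0.01 between genes (camera, adjusted p under 0.05), 17 up and 2 down. With a correlation estimated from these arrays 0 did, where 10 had an unadjusted p under 0.05 and the lowest adjusted p was 0.0749, and fry, which does not set a list against other genes, called 9. As many lists or more shifted in 10 of 100 splits of the arrays, the real one included. The replicate block and the scan day as a block each left 19 shifted. Some lists share members, so their shifts are not separate results. Cxcl10 is in the cytokine and reactive astrocyte lists, Timp1 in the matrix remodelling and reactive astrocyte lists, and Angpt2 in the growth factor and endothelial activation lists. Among the 18 lists that did not shift, the median, the mean and the test differed in sign for neurons, interneurons, astrocytes, endothelium, mural cells, lymphocytes, the thalamic group, interferon response genes and the G2 and M phases. Members named below beyond the 3 largest changes of a list were chosen after their values were seen.

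Of 27 cytokines and chemokines 12 rose and 0 fell (14 over the list alone), with a mean log2 difference of 1.09 (1.33 within scan day 1 and 0.92 within scan day 2; camera adjusted p = 1.08e-24, 0.0749 with an estimated correlation). Of 22 feedback genes of NF-kB and STAT3 signalling 8 rose and 0 fell (12 over the list alone; mean 0.51, 0.63 and 0.43 within the days; adjusted p = 4.75e-17, 0.0749 with an estimated correlation). Among them were the cytokine signalling inhibitor Socs3 (2.80-fold), the oncostatin M receptor Osmr (2.50-fold) and the mRNA decay factor Zfp36 (2.34-fold). Of 19 interferon response genes none passed, with 1 over the list alone (adjusted p of the list 0.58, 0.0149 within scan day 1); Gbp2, the nearest, was 1.49-fold higher (adjusted p = 0.0626, 0.044 with the block). Of 23 genes of reactive astrocytes 7 rose and 0 fell (11 over the list alone; mean 0.61, 0.78 and 0.49 within the days; adjusted p = 4.12e-16, 0.0832 with an estimated correlation), led by Ptx3, the metalloproteinase inhibitor Timp1 (2.70-fold) and the chemokine Cxcl10 (2.69-fold). On their brightest probes alone Osmr (0.04), Zfp36 (0.22), Timp1 (0.16) and Cxcl10 (0.25) did not pass (adjusted p = 1, 0.918, 1 and 0.997). Zfp36 passed in 9 of the 20 settings. With normexp Osmr was at 0.60 and Cxcl10 at 0.70, past the threshold, and Socs3 at 2.20 on its brightest probe, against 1.48.

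Of 32 immediate early genes 8 rose and 0 fell (16 over the list alone; mean 0.54, 0.57 and 0.52 within the days; adjusted p = 4.12e-16, 0.0832 with an estimated correlation), among them Fosb, Atf3 (3.67-fold) and Maff (2.31-fold), and 14 rose with the block. Of 21 heat shock proteins and cochaperones 4 rose, Hspa1a, Hspa1b, the small heat shock protein Hspb1 (2.03-fold) and Hsph1 (1.53-fold), and 0 fell (4 over the list alone; mean 0.43, 0.39 and 0.45 within the days; adjusted p = 1.19e-06, 0.172 with an estimated correlation and 0.0519 within scan day 1). Of 24 genes of the endoplasmic reticulum and integrated stress responses 2 rose, Sdf2l1 (1.61-fold) and the chaperone Hspa5 (1.32-fold, adjusted p = 0.0565 with the block), and 0 fell (2 over the list alone; mean 0.17, 0.19 and 0.16 within the days; adjusted p = 1.69e-05, 0.172 with an estimated correlation). Of 30 hypoxia-inducible genes 3 rose, the neuronal glucose transporter Slc2a3 (1.77-fold), the glycolytic regulator Pfkfb3 (1.74-fold) and the hexokinase Hk2 (1.38-fold), and 0 fell (8 over the list alone; mean 0.17, 0.23 and 0.13 within the days; adjusted p = 4.05e-06, 0.172 with an estimated correlation). Vegfa and Adm made 5 with the block. Of the Hk2 arrays, ipsilateral replicate 2 (−2.79) lay above and contralateral replicate 3 (−3.68) below the other 4 of their groups. Of 25 genes of iron, heme and antioxidant metabolism 1 rose, the heme oxygenase Hmox1 (2.47-fold, adjusted p = 9.42e-05), and 0 fell (3 over the list alone, and 3 with the block, which added Gclc and Srxn1). That list had a mean of 0.13 (0.22 and 0.07 within the days; adjusted p = 0.00931, 0.27 with an estimated correlation and 0.0576 without contralateral replicate 2). The brightest probe of Atf3 differed by 0.03 (adjusted p = 1), and with normexp Atf3 differed by 1.06 and passed. On their brightest probes Sdf2l1, Hspa5, Slc2a3, Pfkfb3 and Hk2 did not pass (adjusted p = 0.16, 0.658, 0.162, 0.312 and 1), nor did Maff on the median of its probes (adjusted p = 0.248). Sdf2l1, Hspa5 and Hk2 passed in 10, 9 and 10 of the 20 settings.

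Of 30 apoptosis regulators 4 rose, the inflammatory caspase Casp4 (2.40-fold), the BH3-only gene Pmaip1 (1.78-fold), and Bcl2a1d (1.79-fold) and Birc3 (1.43-fold), which oppose cell death, and 1, the BH3-only gene Bad, fell (1.35-fold lower; 6 over the list alone). The list had a mean of 0.12 and a median of 0.01 (mean 0.20 and 0.07 within the days; adjusted p = 0.0213, 0.443 with an estimated correlation, 0.107 without contralateral replicate 4, 0.0648 without ipsilateral replicate 2, 0.102 with normexp, 0.0653 on the median of the probes and 0.11 on the brightest probes). Of 18 genes of cholesterol synthesis 4 rose, Mvd (1.66-fold), Hmgcs1 (1.55-fold), Idi1 (1.40-fold) and Msmo1 (1.27-fold, adjusted p = 0.0645 with the block), and 0 fell (10 over the list alone; mean 0.29, 0.34 and 0.26 within the days; adjusted p = 4.78e-12, 0.0749 with an estimated correlation). Of 13 glucocorticoid response genes Cdkn1a and Errfi1 (1.38-fold) rose and Sult1a1 fell (1.57-fold lower), 3 over the list alone, and the list did not shift (adjusted p = 0.3). Casp4 differed by 0.47 with normexp (adjusted p = 0.0454), against 1.26. Bcl2a1d, Mvd, Hmgcs1, Idi1, Errfi1 and Sult1a1 did not pass on their brightest probes (adjusted p = 0.107, 0.103, 0.306, 0.585, 0.775 and 0.127). Of the 20 settings Bcl2a1d passed in 10, Mvd in 13 and Sult1a1 in 11.

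Of 20 genes of endothelial activation 4 rose, the angiopoietin Angpt2 (2.42-fold), Tnfrsf12a (2.03-fold), the cyclooxygenase Ptgs2 (1.93-fold) and the adhesion molecule Icam1 (1.54-fold), and 0 fell (8 over the list alone; 7 rose with the block, which added Edn1, Lcn2 and Ch25h; mean 0.43, 0.55 and 0.34 within the days; adjusted p = 2.37e-09, 0.139 with an estimated correlation). Of 25 coagulation and fibrinolysis genes 5 rose, among them the urokinase receptor Plaur (2.42-fold), Tfpi2 (2.00-fold), Procr (0.58 ± 0.12) and Plau (1.41-fold), and 0 fell (10 over the list alone; mean 0.19, 0.37 and 0.07 within the days; adjusted p = 4.33e-05, 0.346 with an estimated correlation). The brightest probe of Plaur, with a difference of −0.02, did not share the direction of the gene's other 6. Of 25 genes of matrix remodelling 8 rose and 0 fell (10 over the list alone; mean 0.37, 0.503 and 0.275 within the days; adjusted p = 7.08e-09, 0.171 with an estimated correlation), led by the metalloproteinase Mmp3 (3.72-fold), Timp1 and Adamts1 (1.87-fold). Of 26 growth factors and neurotrophins 7 rose and Ntf3 alone fell (12 over the list alone; mean 0.42, 0.55 and 0.34 within the days; adjusted p = 5.23e-08, 0.213 with an estimated correlation). Nptx2, a neuronal pentraxin, was 4.37-fold higher, with 8 of its 9 probes up and the brightest at −0.22, and Gdf15 was 2.62-fold higher. Under normexp Angpt2 was at 0.48 (adjusted p = 0.016), Plaur at 0.60 (0.0263) and Gdf15 at 0.75 (0.0142), against 1.27, 1.28 and 1.39. Mmp3 did not pass on its brightest probe (0.31, adjusted p = 1), with the filter on all 10 arrays (0.859) or with normexp (0.0713). Tfpi2, Adamts1 and Ptgs2 did not pass on theirs (adjusted p = 1, 0.0673 and 0.134). Tfpi2 passed in 8 and Ptgs2 in 14 of the 20 settings.

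Among markers of resident brain cells, the lists of neurons, interneurons, glutamate receptors and ion channels, astrocytes, microglia, oligodendrocytes, endothelium and mural cells did not shift (adjusted p = 0.812, 0.0749, 0.58, 0.969, 0.276, 0.321, 0.938 and 0.914), with 1, 5, 0, 0, 3, 0, 3 and 0 members past over the list alone. The interneuron list passed without contralateral replicate 1 (adjusted p = 0.0456) or 5 (0.0362), with normexp (0.0275), without number 5 (0.0295) and without numbers 1 and 5 (0.0205). The receptors and channels passed, lower, without ipsilateral replicate 5 (0.0284), without number 5 (0.0294), without numbers 1 and 5 (0.0133), on the brightest probes (0.0287) and within scan day 1 (0.000695). The oligodendrocyte list passed, also lower, with array weights (0.0377). Single members did change. Of 21 neuronal markers 1 fell, the cortical transcription factor Neurod6 (1.56-fold lower). Of 14 interneuron markers the vesicular GABA transporter Slc32a1 (1.28-fold) and Reln (1.25-fold) rose, joined by Gad1 and Gad2 with the block. The value of ipsilateral replicate 2 for Slc32a1, 0.47, lay above its group's others, the highest of which was 0.36. Of 19 microglial markers Selplg fell (1.40-fold lower), with contralateral replicate 2 at −2.07 below its group's others, the lowest of which was −1.73, and P2ry12 also fell with the block. Of 16 endothelial markers Cdh5 rose (1.31-fold) and the transporter Slco1a4 fell (1.52-fold lower, adjusted p = 0.0749 with the block). In the 20 settings Neurod6 passed in 20, Slc32a1 in 12, Slco1a4 in 11, Reln and Cdh5 in 10 and Selplg in 9. Of 36 receptors and channels none passed, and 1, Kcnv1, fell with the block; Kcnj3, nearest to passing, differed by −0.24 ± 0.08. Of 15 astrocyte, 16 oligodendrocyte and 14 mural cell markers none passed; Gfap differed by 0.40 ± 0.18, Olig1 by −0.37 ± 0.17 with contralateral replicate 2 at 2.76 against 3.43 or more in the others, and Kcnj8 by 0.28 ± 0.10. The 16 reference genes did not shift (adjusted p = 0.803), and none passed, singly or over the list alone.

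Blood cell markers gave few calls. Of 17 neutrophil markers 1 rose, Clec4d (3.36-fold, a receptor of myeloid cells; 1 over the list alone), and with the block Il1r2 and S100a9 passed too. The list shifted up (mean 0.27, 0.54 and 0.10 within the days; adjusted p = 0.00698, 0.453 with an estimated correlation, 0.061 without ipsilateral replicate 1, 0.0774 with the filter on all 10 arrays and 0.253 within scan day 2). Clec4d differed by 0.30 on its brightest probe (adjusted p = 0.897) and with that filter (adjusted p = 0.539), and by 0.47 with normexp (adjusted p = 0.0295). Of 17 monocyte and macrophage markers 1 rose, Cd14 (4.33-fold, adjusted p = 7.76e-06; 1 over the list alone), a receptor for bacterial lipopolysaccharide that microglia also express (1.45 with normexp, against 2.11), and the list did not shift (adjusted p = 0.167, 0.0332 without contralateral replicate 5 and 0.0164 within scan day 1). The 14 lymphocyte markers and the 16 erythroid and platelet genes had 0 past, also over the list alone, and did not shift (adjusted p = 0.814 and 0.167). Both lists were higher within scan day 1 (adjusted p = 0.00311 and 0.00051) and not within scan day 2 (0.253 and 0.862), and the erythroid list also passed without contralateral replicate 3 (0.0307), ipsilateral replicate 5 (0.0108) or number 5 (0.0244) and on the brightest probes (0.0203). Cd79a differed by −0.16 ± 0.11 and Pf4 by 0.42 ± 0.13.

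**Figure D3:**
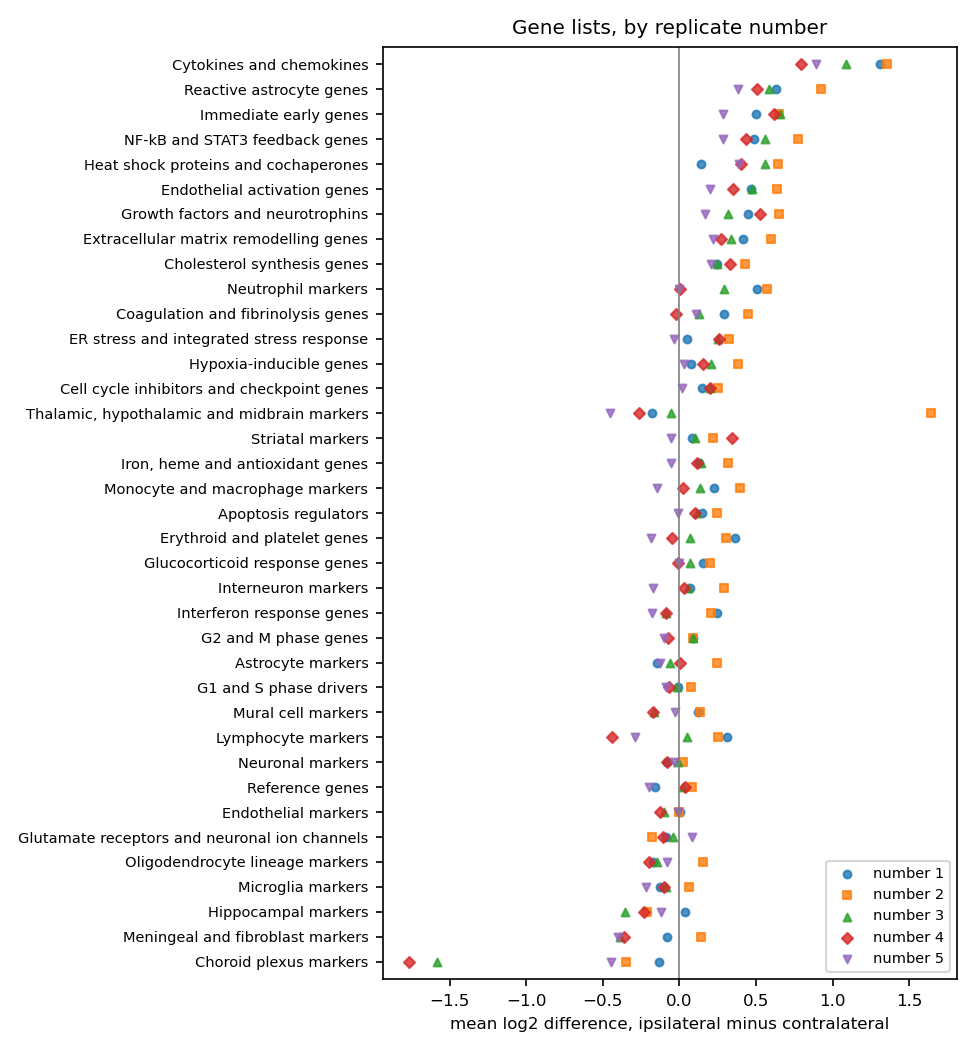
The mean log2 difference, ipsilateral minus contralateral, over the genes of each of the 37 lists (x axis), with 1 marker per replicate number. Lists are ordered by their mean over the numbers, with cytokines and chemokines at the top, between 0.79 and 1.35, and choroid plexus markers at the bottom, between −1.77 and −0.13.

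Markers of adjoining tissues and regions differed between replicate numbers. All 14 choroid plexus markers were lower on average (list mean −0.86, −0.24 and −1.26 within the days; adjusted p = 4.33e-05, 0.477 with an estimated correlation; 0.000294 and 0.526 without numbers 3 and 4), and none passed singly or over the list alone, with Kcne2, a potassium channel subunit, nearest (−1.35 ± 0.38, adjusted p = 0.105, 0.0464 with the block). The list mean was −1.58 in number 3 and −1.77 in number 4, against −0.13, −0.35 and −0.45 in numbers 1, 2 and 5. Of 17 meningeal and fibroblast markers 14 were lower, with none past singly or over the list alone; the list mean was −0.22 (0.03 and −0.38 within the days; adjusted p = 0.0119, 0.706 with an estimated correlation, 0.108 without ipsilateral replicate 3, 0.161 without numbers 3 and 4 and 0.753 within scan day 1), and Slc6a20a differed by −0.34 ± 0.10. Of 15 striatal markers none passed, singly or over the list alone, and the list shifted up (mean 0.14, 0.15 and 0.13 within the days; adjusted p = 0.0119, 0.562 with an estimated correlation, 0.185 without contralateral replicate 4, 0.108 without ipsilateral replicate 3, 0.141 without numbers 3 and 4, 0.106 with array weights and 0.16 within scan day 1); Pdyn differed by 0.45 ± 0.16 (adjusted p = 0.19, 0.0341 with the block). Of 20 thalamic, hypothalamic and midbrain markers Rgs16 rose (1.77-fold; 1 over the list alone) and the list did not shift (adjusted p = 0.373, 0.000695 within scan day 1 and 0.0176 without numbers 3 and 4), but its mean was 1.64 in number 2 against −0.45 to −0.05 in the other 4. Of 15 hippocampal markers Wfs1 rose (1.40-fold; 1 over the list alone), Tdo2 fell with the block, and the list did not shift (adjusted p = 0.58). Neither Rgs16 nor Wfs1 passed on its brightest probe (adjusted p = 0.12 and 0.66). Pituitary hormone genes, examined after their values were seen, differed far more between arrays than between hemispheres, with Gh from −4.83 to 7.57 and an adjusted p of 0.859.

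**Figure D4:**
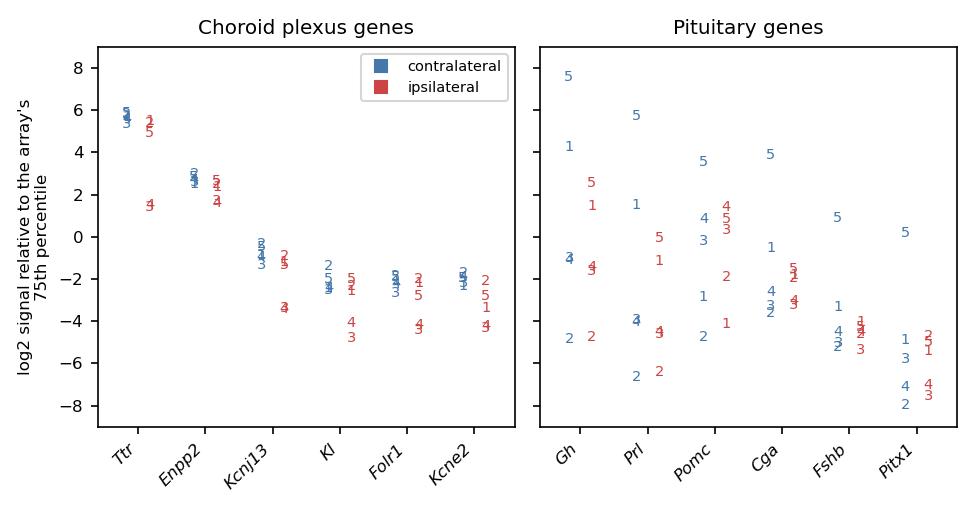
The log2 signal relative to each array's 75th percentile (y axis) for 6 choroid plexus genes (left) and 6 pituitary genes (right), each digit marking the replicate number of an array, contralateral in blue and ipsilateral in red. For Ttr the ipsilateral arrays 3 and 4 lie at 1.42 and 1.52 and the other 8 between 4.95 and 5.86. Gh, Prl, Pomc, Cga, Fshb and Pitx1 are highest on contralateral array 5.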

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

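The tests of the 3 patterns weighed here, the choroid plexus, the pituitary and the genes that follow the replicate number, were chosen only after the result was seen, whereas the count of outlying arrays followed a rule fixed in advance.

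Over 184 groups of 5 arrays, 2 for each of 92 named genes, 10 had an array far from the other 4, by a gap of over 0.71 of the group's range, where 9.2 would by chance, and 9 of the 10 are given here. Fosb was low in ipsilateral replicate 5 (−1.67). Gadd45g was low on the same array (0.52). Ankrd34c was high in contralateral replicate 4 (−2.35). Ddit4l was low in ipsilateral replicate 2 (−1.64). Hk2 was high in ipsilateral replicate 2 (−2.79) and low in contralateral replicate 3 (−3.68). Slc32a1 was high in ipsilateral replicate 2 (0.47). Selplg and Olig1 were low in contralateral replicate 2 (−2.07 and 2.76). Among 21061 kept probes without a gene symbol, which the comparison of genes leaves out, 71 differed between the hemispheres when each probe was tested by itself, 47 higher and 24 lower.

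Choroid plexus markers were lower in the ipsilateral hemisphere, and 1 of them, F5, is also in the list of coagulation genes. The median difference of the 14 markers was −0.18 over numbers 1 and 2, −1.61 over numbers 3 and 4 and −0.37 in number 5. That argues against a like response in every animal. Numbers 3 and 4 were set apart for their large falls, so part of the gap follows from that choice. Less choroid plexus tissue in these ipsilateral samples of whole tissue, taken with no sort, is a candidate explanation for the larger falls of numbers 3 and 4. Of the 14 markers, 13 had these as the 2 lowest of 10 arrays, the abundant Ttr at 1.42 and 1.52 against at least 4.95 on every other array. The samples were singled out by these low values, so the count cannot tell less tissue from lower expression. A stronger response in those animals would have given them the 2 largest mean rises of the cytokine list, which was not seen. The list rose by a mean of 0.94 in numbers 3 and 4 and 1.18 in the other 3. By number it was 1.085 in number 3 and 0.79 in number 4, against 1.31, 1.35 and 0.89 in numbers 1, 2 and 5. As number 3 was not below the median of the numbers, that explanation stays open. Whether less tissue accounts for the whole shift stays open. Without numbers 3 and 4 all 14 markers were still lower, by a mean of −0.31. The list then passed at the preset correlation (camera adjusted p = 0.000294) but not with an estimated one (adjusted p = 0.526).

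Several pituitary genes lay far apart between arrays, while others, such as Lhb, varied less. Pituitary tissue carried into some samples is a candidate source, since 9 of the 13 listed genes other than Gh were highest on contralateral array 5, where Gh was highest. On that array Gh was at 7.57, Prl at 5.72, Cga at 3.87 and Pomc at 3.56, against at most 4.25, 1.502, −0.51 and 1.40 on the others, and 1 of the 14 genes, Pomc, is also in the hypothalamic list. An effect of the slide equal on both of its arrays would not give the median difference of 2.59 between the 2 arrays of that slide. That array was chosen for its high Gh, which favours such a difference. Gh also followed the number in part, at 2.56 on ipsilateral array 5 and at −4.83 and −4.73 on the arrays of number 2. A part shared by the arrays of a slide therefore stays open. In limma's fit 0 of the 14 passed between hemispheres, also at an unadjusted p under 0.05.

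There were 31 genes that differed by over 2 log2 units between replicate numbers and by under 0.7 within each number. Cwc22 was higher by 3.26 in number 3 on 13 of 13 probes, and Snhg12 differed there by −2.87. Baiap2l1 and Fggy stood apart on 9 of 12 and 14 of 17 probes. Many of the 31 rested on 1 probe with a low signal, such as Olfr116 at a mean level of −5.0 and Vmn2r28 at −4.1. The 31 genes shifted by a median of 1.68, a size that follows from their choice. The 200 genes nearest in level were not so chosen and shifted by a median of 0.14. That argues against a shift of the slide shared by genes of like brightness as the main source of these 31 genes. That both hemispheres of a number belong to 1 animal may account for them, since of the 120 assignments of ipsilateral numbers the highest other gave 26 genes, and, counted only after that, the highest of the 44 with no number in place gave 7. An effect of the slide on single probes shares the number with the animal and stays open, and no biological difference between animals was tested.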

How the results depend on the processing

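The tests with the scan day as a block, each scan day alone, numbers 3 and 4 left out, number 5 left out, numbers 1 and 5 left out, the block with an estimated correlation, and the splits counted list by list were chosen only after the result was seen.

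No setting turned the direction of any of the 19 shifted lists. Against 463 genes (323 higher, 140 lower) and 9 cell cycle genes, the median of a gene's probes gave 291 genes, 68 of them lower, and the brightest probe 87 (58 higher, 29 lower) with 3 cell cycle genes. Array weights gave 1149 (673 higher, 476 lower) with 14 cell cycle genes. The replicate block, which is the same fit as the slide block, gave 774 (526 higher, 248 lower). Scan day 1 alone gave 10 higher, 0 lower and 0 cell cycle genes, and scan day 2 alone 13, 0 and 0, where 1182 and 1927 genes (11 and 18 of the cell cycle) had an unadjusted p under 0.05 in limma; these fits hold fewer arrays. Without numbers 3 and 4 it was 2 higher, 0 lower and 0 cell cycle genes (1123 unadjusted, 12 of the cell cycle), without number 5 the lower count was 65, and without numbers 1 and 5 it was 100 genes, 95 higher, 5 lower and 3 of the cell cycle. A 1.5-fold threshold left 208 genes, and single probes gave 1352 of 199147. Quantile scaling (590), median scaling (449), normexp (345), no filter (410), the filter on all 10 arrays (445), the series table (584), the variance trend (569) and the scan day block (445) stayed within 1.5 times. Of the 37 lists, 0 shifted with an estimated correlation, 0 with the block and an estimated correlation (8 at an unadjusted p under 0.05), and 9 with fry; other settings gave 16 to 22. Leaving out each array in turn gave 201 to 661 genes, 159 to 467 higher, 36 to 194 lower, 2 to 10 cell cycle genes and 16 to 21 lists. Of the 75 named genes past the threshold, 22 stayed past it under every planned setting without a block, the block kept 71 (it lost Btg3, Cenpe, Hspa5 and Slco1a4, gained Ccnd1, Gbp2, Kcne2 and Pdyn, and changed no other call of a named gene or a list), and leaving out an array kept 53 to 75.

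None of the 463 genes turned under a setting except the brightest probe, where 23 did, and of the named ones Nptx2 was −0.22 and Plaur −0.019 there; the uncalled Cd79a was 0.030, Slc6a20a 0.129, Cdk1 0.040, Mki67 −0.229 and Pcna 0.010. Pcna, at −0.02, was 0.016 under quantile scaling and 0.013 with the series table and with array weights, and ran from −0.080 to 0.050 as each array was left out (0.021 and 0.023 without contralateral replicates 1 and 5, 0.027 and 0.050 without ipsilateral replicates 2 and 5). Mki67 was −0.039 under normexp. Trp53, at 0.05, ran from −0.038 to 0.196 as each array was left out (−0.023 without contralateral replicate 2, −0.038 and −0.016 without ipsilateral replicates 1 and 3). Apart from the brightest probe, which drops all other probes of a gene, and the fits with fewer arrays, the cause was not tested. Signal over background limits the dimmest probes, as 82.1% to 88.0% of an array's spots were well above it.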

Other observations

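The tests of transcript records and the splits counted list by list were chosen only after the result was seen, whereas the splits for the counts of genes, cell cycle genes and lists were planned.

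Of 1631 genes with several transcript records, 1 had records that differed in their response after adjustment. At an unadjusted p under 0.05 there were 59, no more than chance alone would give. Gprc5c, an orphan receptor chosen after its values were seen, had a record of 5 probes that differed by 1.504 between the hemispheres and another of 2 probes that differed by 0.616 (adjusted p = 0.00371 for the difference between records, higher in 5 and 4 of the 5 replicate numbers). The 5 probes ran from −0.02 to 2.22, the other 2 from 0.547 to 0.685, and the gene as a whole did not pass (adjusted p = 0.0524). With the replicate block Tpm1, Lrrfip1, Dmkn and Mrtfb passed as well, making 5. The record of 8 probes of Tpm1, a tropomyosin, differed by 0.96 and its other by 0.22. Homer1, a postsynaptic scaffold whose short form is induced by neuronal activity, did not pass (adjusted p = 0.22, 0.147 with the block), with a record of 7 probes at 0.80, each between 0.67 and 1.36, and another of 7 probes at −0.07.

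The arrays were also split at random into 5 and 5, 100 of the 126 ways, to see what counts arise under other groupings. The other splits leave the difference between hemispheres in the spread within their groups, which lowers their counts. The real split gave 463 genes, and 1 of 100, the real one, gave as many, with 1 gene in the highest other. That share ignores the pairing of the arrays by number. The 16 splits that part every pair can give no share under 0.0625, so chance is not excluded for that count. The same held for the 323 higher genes (1 of 100, highest other 1), the 140 lower genes (1 of 100, highest other 1) and the 9 cell cycle genes (1 of 100, highest other 0). As the other splits called at most 1 gene in all, their cell cycle count could hardly differ from 0. It therefore says nothing of cell cycle genes in particular. For the 19 shifted lists chance cannot be excluded, because 10 of 100 splits gave as many and the highest other gave 22. Of the 16 splits that, like the real one, part every pair of arrays of a number, none but the real one called a gene (463, and 774 with the block, against 0), and 4 shifted as many lists, the highest other 22 without the block and 20 with it. The other splits leave pairs together and so carry differences between the numbers. Counted list by list, 10 of the 19 had a p as small in under 0.05 of the splits. These were cytokines and chemokines, NF-kB and STAT3 feedback, immediate early, reactive astrocyte, cholesterol synthesis, endothelial activation, matrix remodelling and coagulation genes (1 of 100 each), growth factors (2) and cell cycle inhibitors and checkpoint genes (3). For hypoxia-inducible genes it was 7, for iron and heme genes 8, apoptosis 8, heat shock 10, the endoplasmic reticulum 12, neutrophils 12, meninges 34, choroid plexus 38 and striatum 39. Over the 16 splits that part every pair, too few for a share under 0.05, 10 of the 19 had their smallest p in the real split, and 9 with the block. These 10 were cytokines, NF-kB and STAT3 feedback, immediate early, reactive astrocyte, cholesterol synthesis, endothelial activation, matrix remodelling, coagulation, growth factor and, without the block alone, apoptosis genes, whereas cell cycle inhibitors had a p as small in 2.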
